A study of Mus musculus with 9 samples.

How the data were processed

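The 9 samples are gastrocnemius muscles of female C57BL/6 mice, grouped by their labels into Normal, Cisplatin and RP with 3 samples each. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA went into a Lexogen QuantSeq 3′ library, a method that reads 1 tag near the end of each transcript, so that counts are not scaled by gene length. The authors deposited 1 table of raw read counts per sample, with a gene symbol and a count on each of 23282 rows. Per the submitters' processing notes, Bowtie2 and edgeR were used with the mm10 genome build; their versions, the counting program, its strand setting and the annotation are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and near-identical genes such as the globins may share reads.

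From the deposited counts, 79 rows that share 35 symbols were summed, which left 23238 symbols, 5145 of them at 0 in every library. Library totals were 8196030 to 10678342 counts, and genes with a few counts carry wide counting error. Counting intervals (exact Clopper-Pearson, 95%) and floors of 3 counts over a group cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before averaging: chi-square per degree of freedom was 11.3 to 28.9 within groups, more than counting error alone gives, and no pair matched as copies would.

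The test was fixed before the data were examined: edgeR 4.0.16 in R 4.3.3, with filterByExpr by group (12859 genes kept), TMM scaling, glmQLFit on all 9 libraries with 1 coefficient per group, glmQLFTest for each of 3 comparisons, and a Benjamini-Hochberg adjusted p under 0.05. SEs were computed as the log2 fold change divided by the square root of the F statistic. The median log2 fold change over all genes was -0.08, 0.07 and -0.01 in Cisplatin against Normal, RP against Cisplatin and RP against Normal. With library size as the only scaling, these medians were -0.15, 0.21 and 0.06, and changes are reported relative to the TMM scale. The 32 gene lists, also fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry beside it. Camera sets a list against the other genes tested, whereas fry asks only whether the list's own members changed.

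Named genes followed a rule fixed in advance: Fbxo32 and Trim63; the 12 genes of largest rise and fall per comparison among called genes with non-overlapping groups and a mean of at least 5 CPM, leaving out unnamed gene models; up to 4 called members of each list by p; and up to 12 genes of opposite sign in Cisplatin against Normal and RP against Cisplatin. Rn45s, Cblb, Trim32, Trim55, Fbxo21, Mstn, Kera and Ccl8, and the individual values of Myl3, were named in addition, after their values were seen. Positions are those of GENCODE M21 on GRCm38, the assembly that mm10 names; 54 of 56 symbols looked up had a single position.

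The procedure was tested on simulated data, with counts drawn from the Normal means, the fitted dispersions and the real library sizes, which left 12574 genes after filtering. In the simulated comparison of Cisplatin with Normal, 49 of 100 genes changed by a log2 of 1 and 88 of 100 changed by 2 were recovered, and 7 of 12374 unchanged genes were called. The simulated RP against Cisplatin gave 26 and 44 of 50, and RP against Normal 22 and 41 of 50. Most genes were left unchanged in these simulations, and recovery with a majority of genes changed was not simulated. A proteasome list raised by a log2 of 1 was called, and 0 of 30 other lists were. Each gene was drawn independently, so this does not show how many lists camera calls when genes vary together. In Cisplatin against Normal the correlation estimated between the real proteasome genes was 0.551.

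Alternatives were RLE scaling, no filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fits of the 2 compared groups alone, the replicate number as a block, and leaving out each library in turn. Leaving out Rn45s and using its share as a covariate were added after seeing the data, as was leaving out Hbb-b1 and Hbb-b2, which almost repeat the counts of Hbb-bs and Hbb-bt. So were parting a shared group between 2 comparisons, with the parts as separate groups of 1 and 2 libraries, and leaving out each library with an estimated correlation. Unchanged groups that share libraries were simulated 20 times from the Normal means and the fitted dispersions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.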

Results

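Gene expression was measured by 3′ RNA sequencing in the gastrocnemius muscle of female C57BL/6 mice, an inbred laboratory strain, given as 4 weeks of age. The 9 libraries fell into 3 groups of 3. The Normal group received saline injections and water by mouth. The Cisplatin group received 4 injections of cisplatin, a platinum drug that crosslinks DNA, at 3 mg/kg into the peritoneum, with water by mouth for 9 days. The RP group received the same cisplatin injections together with 100 mg/kg RP by mouth for 9 days; the series title concerns an extract of the peony Paeonia lactiflora and the E3 ubiquitin ligases of wasting muscle. Total counts ran from 8196030 to 8677236 per library in Normal, from 8352397 to 10678342 in Cisplatin and from 9178613 to 9826089 in RP. Between 14756 and 15527 genes had at least 1 count. The precursor ribosomal RNA Rn45s took 12.6 to 12.8% of the counts in Normal, 9.23 to 12.1% in Cisplatin and 7.38 to 11.8% in RP. Values are TMM-scaled CPM, mean ± SD over 3 libraries, with log2 fold changes as the edgeR estimate ± SE with Benjamini-Hochberg adjusted p.

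The comparison of Cisplatin with Normal asks what the drug did to the muscle transcriptome, in particular to the muscle-specific ubiquitin ligases named in the series title. Fbxo32 (atrogin-1) and Trim63 (MuRF1), the E3 ligases that mark muscle atrophy, rose together. Fbxo32, at chromosome 15, 58175879 to 58214932 on the minus strand of GRCm38, went from 383 ± 77.1 CPM in Normal to 10076 ± 1860 in Cisplatin, a log2 fold change of 4.72 ± 0.30 (adjusted p = 7.85e-08). Trim63, at chromosome 4, 134315120 to 134329629 on the plus strand, went from 545 ± 98.9 to 10335 ± 1335 CPM, a log2 fold change of 4.25 ± 0.23 (adjusted p = 4.56e-08). Of the 20 muscle E3 ligases tested, 9 rose, 3 fell and 8 were not called. In this comparison 54.5% of all genes tested were called, the share against which counts of list members are to be read. Fbxo31 (2.81), Trim54 (1.87) and Cblb (1.45) were among the other risers, while Fbxo21 (-1.10), Trim32 (-1.02) and Trim55 (-0.70) fell. The list median was 0.46 (camera adjusted p = 0.000385, and adjusted p = 0.182 with an estimated correlation). Each Cisplatin library lay above each Normal library for both Fbxo32 and Trim63. Fallen ligases numbered 1 without Normal replicate 2.

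The proteasome, which degrades ubiquitinated proteins, rose almost as a whole: 36 of 38 proteasome and ubiquitin genes rose and none fell, with a median log2 fold change of 1.53 (camera adjusted p = 4.50e-28, and adjusted p = 0.144 with an estimated correlation). Psmd8 rose from 172 ± 4.35 to 1228 ± 175 CPM, and Psmd2 (2.19), Psmd11 (2.29) and Psma7 (2.41) rose as well. Of 25 autophagy and lysosome genes, 15 rose and 0 fell, among them Bnip3 (2.53), the cathepsin gene Ctsl (2.12) and Gabarapl1 (2.52), with a median of 0.68 (camera adjusted p = 1.10e-06, and adjusted p = 0.144 with an estimated correlation). Among 25 glucocorticoid and FoxO responsive genes, 18 rose and 2 fell (median 1.37, camera adjusted p = 1.43e-08, and adjusted p = 0.144 with an estimated correlation). The translation repressor Eif4ebp1 (3.59) and Sesn1 (3.21) were among the risen genes. Of the 25 members of this list, 7 also belong to another list. With p adjusted over the list alone, 37 proteasome genes rose, and the counts of the other 3 lists, E3 ligases included, were the same.

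Metal-binding, p53 and stress genes rose. The metallothionein genes Mt2 and Mt1, whose proteins bind heavy metals, rose to 8171 ± 1113 and 11090 ± 1696 CPM, log2 fold changes of 7.09 ± 0.49 and 6.72 ± 0.42 (adjusted p = 1.51e-07 and 7.85e-08). Among genes with a mean of at least 5 CPM and non-overlapping groups these were the largest rises, followed by Lcn2 (6.64), Chil3 (6.44), Acot1 (5.48), Gdf15 (5.44) and Cdkn1a (5.32). Of 28 p53 and DNA damage genes, 21 rose and 2 fell (median 1.32, camera adjusted p = 3.23e-07, and adjusted p = 0.144 with an estimated correlation). Cdkn1a, the cyclin-dependent kinase inhibitor p21, went from 34.5 ± 7.19 to 1384 ± 104 CPM, and Trp53inp1 rose by 3.01; Ccng1 (-1.23) and Ddit4l (-2.44) were the members that fell. In the antioxidant and metal list 15 of 21 rose and 5 fell (median 0.72, camera adjusted p = 4.47e-05, and adjusted p = 0.102 with an estimated correlation), with Gclm at 2.52 and Sod1 at 1.74. Of 16 integrated stress and unfolded protein genes, 8 rose and 2 fell (median 0.48, camera adjusted p = 0.00748, and adjusted p = 0.144 with an estimated correlation), including Xbp1 (1.53) and Atf4 (1.71). Heat shock genes rose in 10 of 18 cases and fell in 1 (median 0.50, camera adjusted p = 0.00139, and adjusted p = 0.261 with an estimated correlation), with Hspb1 going from 361 ± 17.7 to 4085 ± 662 CPM. With p adjusted over the list alone, 11 heat shock genes rose, and the counts of the other 3 lists were the same.

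**Figure D1:**
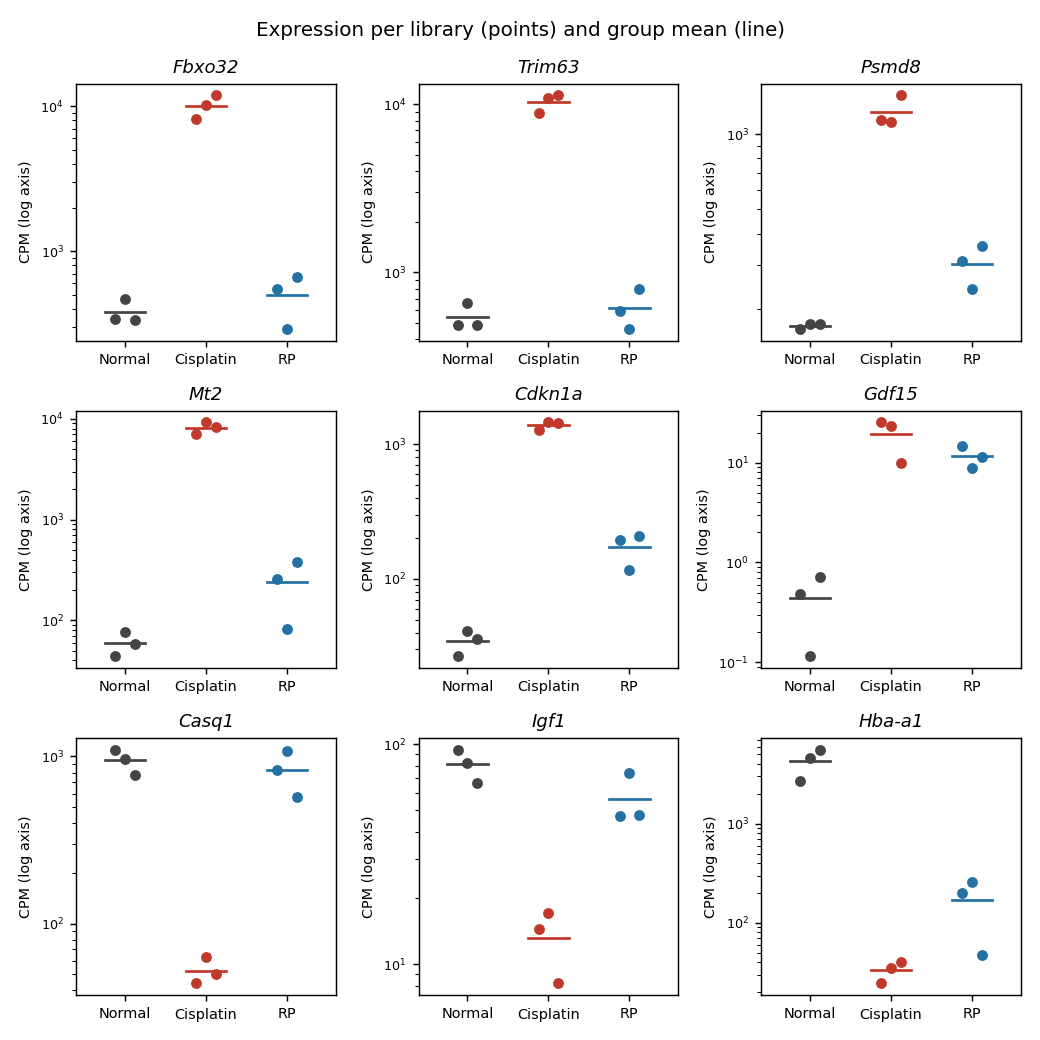
Expression of 9 genes in each library, in CPM on a log axis, with a line at each group mean (n = 3). Fbxo32 and Trim63 in RP lay 0.39 and 0.18 from Normal on the log2 scale (0.14 to 0.66 and -0.05 to 0.35 with 1 library left out) and were not called, Cdkn1a and Gdf15 stayed above it (2.33 and 4.69 on the log2 scale), and Hba-a1 stayed below it (-4.68).

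Fast fibre, glycolysis and oxidative phosphorylation genes fell in Cisplatin. Of 18 fast fibre genes 10 fell and 1 rose (median -0.66, camera adjusted p = 0.00120, and adjusted p = 0.338 with an estimated correlation). Casq1, the calsequestrin of fast fibres, dropped from 948 ± 162 to 52.2 ± 9.61 CPM, and Tpm1 (-1.47) and Myl1 (-1.49) fell too. Of 16 slow fibre genes, 11 fell and 2 rose, Ankrd2 (3.48) and Myh7b (1.14), with a median of -2.29. The slow fibre list was not called (camera adjusted p = 0.133, and adjusted p = 0.633 with an estimated correlation). It was called without Cisplatin replicate 1 (0.0203) or without Normal replicate 2 (0.000891), within a range of 0.000891 to 0.633 over the alternatives. Casq2, the calsequestrin of slow fibres, fell by 3.26 on the log2 scale. Glycolysis and glycogen genes fell in 12 of 20 cases and rose in 3 (median -0.83, camera adjusted p = 3.09e-05, and adjusted p = 0.144 with an estimated correlation), with Gpd1 going from 316 ± 41.0 to 37.6 ± 3.11 CPM. Of 76 oxidative phosphorylation genes 45 fell and 3 rose (median -0.48, camera adjusted p = 0.000113, and adjusted p = 0.542 with an estimated correlation), such as Cycs (-1.17) and Cox7a1 (-1.11). Fatty acid genes went up in 14 of 28 cases and down in 1 (median 0.43, camera adjusted p = 7.01e-05, and adjusted p = 0.402 with an estimated correlation), with the mitochondrial uncoupling protein gene Ucp3 at 1.95. Counts adjusted over the list alone were 13 fallen slow fibre genes and 51 fallen oxidative phosphorylation genes, and those of the fast fibre, glycolysis and fatty acid lists were the same. Fallen slow fibre genes numbered 5 without Normal replicate 3 and 6 without Cisplatin replicate 2 or 3. Risen oxidative phosphorylation genes numbered 1 without Normal replicate 1 or 2 or Cisplatin replicate 3. Risen fatty acid genes numbered 22 without Normal replicate 3. Risen fast fibre genes numbered 2 with DESeq2 and 0 without Normal replicate 1.

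Growth factor, myogenic and clock genes split in both directions. Igf1, a growth factor for muscle, fell from 81.1 ± 14.0 to 13.2 ± 4.53 CPM, Igfbp5 fell by 4.00 and Smad3 by 2.41 on the log2 scale, while Akt1 rose by 1.63. The myostatin gene Mstn was at 48.7 ± 21.9 and 47.7 ± 2.55 CPM (adjusted p = 0.922). In this signalling list 9 of 25 rose and 10 fell (camera adjusted p = 0.373, and adjusted p = 0.542 with an estimated correlation). Of 19 satellite cell and embryonic muscle genes, 8 fell and 3 rose (median -0.64, camera adjusted p = 0.0247, and adjusted p = 0.144 with an estimated correlation), with Actc1 at -4.86 and Mef2c at -2.75. Denervation and neuromuscular junction genes, below called the neuromuscular junction list, fell in 6 of 12 cases, Ache (-3.32) among them. They rose in 2, Musk (2.73) and Gadd45a (1.34), which is also in the p53 and DNA damage list. The neuromuscular junction list was not called (camera adjusted p = 0.597, and adjusted p = 0.680 with an estimated correlation). In the circadian list 8 of 17 rose and 7 fell (camera adjusted p = 0.564, and adjusted p = 0.623 with an estimated correlation): Dbp fell from 105 ± 16.5 to 4.66 ± 0.751 CPM and Arntl rose by 2.77. The labels give neither the time of day of tissue collection nor its interval from the last injection, so in each comparison a difference in collection time was not separated from the treatment for clock genes. Immediate early genes rose in 8 and fell in 6 of 20 cases, with a median of 0.13 and a mean of -0.14 (camera adjusted p = 0.775, and adjusted p = 0.911 with an estimated correlation). Cell cycle genes rose in 5 and fell in 3 of 15 (camera adjusted p = 0.293, and adjusted p = 0.467 with an estimated correlation). Counts adjusted over the list alone were 9 risen immediate early genes and 4 risen cell cycle genes, and those of the growth factor, satellite cell, neuromuscular junction and circadian lists were the same. Risen satellite cell genes numbered 1 without Normal replicate 1 or Cisplatin replicate 2. Risen immediate early genes numbered 4 without Normal replicate 3 and 5 without Cisplatin replicate 2.

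Erythroid, tendon, collagen, fibroblast, adipocyte and lymphocyte lists fell in Cisplatin. All 7 erythroid genes fell (median -7.49, camera adjusted p = 3.20e-08, and adjusted p = 0.144 with an estimated correlation): Hba-a1, a haemoglobin alpha chain gene, went from 4316 ± 1468 to 33.2 ± 7.94 CPM, and Hba-a2 had 1762 counts over the Normal group and 3 over Cisplatin, a ratio of 638 (95% counting interval 218 to 3099). The globin genes are near-identical copies, and how reads were divided between them is uncertain. Over the 9 libraries Hbb-b1 held 98.7% of the count of Hbb-bs, and Hbb-b2 95.2% of that of Hbb-bt, so the 7 symbols are not 7 separate measurements. Without Hbb-b1 and Hbb-b2, a test chosen after seeing the data, 5 of the 5 others fell (median -7.49, camera adjusted p = 1.32e-06, and adjusted p = 0.139 with an estimated correlation). All 9 tendon markers fell (median -5.55, camera adjusted p = 5.01e-08, and adjusted p = 0.144 with an estimated correlation), as Fmod did by 5.55 on the log2 scale; Kera had no count in Cisplatin and was at least 92.4-fold lower there, against a floor of 3 counts over the group. With Kera at that bound the tendon median was unchanged at -5.55. Collagen and matrix genes fell in 23 and rose in 2 of 28 cases (median -3.39, camera adjusted p = 1.98e-12, and adjusted p = 0.173 with an estimated correlation), with Lum at -5.30 and Col6a3 at -4.88. Fibroblast and fibro-adipogenic progenitor markers fell in 13 of 15 (median -2.92, camera adjusted p = 4.61e-13, and adjusted p = 0.144 with an estimated correlation) and adipocyte markers in 11 of 13, with 1 rising (median -2.64, camera adjusted p = 0.000385, and adjusted p = 0.393 with an estimated correlation). Of the 20 members of the lymphocyte list only 6 passed the filter, here and in the later comparisons. In Cisplatin 5 of the 6 fell (median -5.30, camera adjusted p = 9.10e-08, and adjusted p = 0.144 with an estimated correlation). The antigen presentation genes Cd74 (-5.30), H2-Eb1 (-5.72), H2-Ab1 and H2-Aa were among the 5, so the list result rests largely on them. For these 6 lists the counts adjusted over the list alone were the same. Risen collagen and matrix genes numbered 1 without Normal replicate 1 or 3 or Cisplatin replicate 3.

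Macrophage markers fell in 15 and rose in 2 of 18 cases (median -1.75, camera adjusted p = 0.000369, and adjusted p = 0.393 with an estimated correlation), with Csf1r at -3.10 and the lysosomal Cd68 at 2.22. Smooth muscle and pericyte markers fell in 10 and rose in 1 of 12 (median -1.48, camera adjusted p = 0.000169, and adjusted p = 0.144 with an estimated correlation). Endothelial markers fell in 8 and rose in 3 of 15 cases (median -0.61, camera adjusted p = 0.157, and adjusted p = 0.623 with an estimated correlation), Ptprb being at -1.29 and Cldn5 at 1.92. That list was called without Cisplatin replicate 1 (0.0485), within a range of 0.0328 to 0.623. Schwann cell markers fell in 6 of 12 (median -1.31, camera adjusted p = 0.0284, and adjusted p = 0.487 with an estimated correlation), a call lost without Cisplatin replicate 2 (0.0511) or without Normal replicate 2 (0.0739), within a range of 0.00722 to 0.487. Neutrophil markers rose in 2 of 6, Lcn2 and Retnlg (3.79), and the list was not called (camera adjusted p = 0.0853, and adjusted p = 0.467 with an estimated correlation). It was called without Cisplatin replicate 3 (0.0281), within a range of 0.0270 to 0.467. Interferon response genes fell in 13 of 27 cases and none rose (median -0.93, camera adjusted p = 0.0113, and adjusted p = 0.542 with an estimated correlation), for example Psmb9 (-2.52) and Igtp (-1.67), a list call lost without Cisplatin replicate 3 (0.0557), within a range of 0.00171 to 0.543. Inflammatory and NF-kB genes rose in 12 and fell in 2 of 19 cases (median 1.57, camera adjusted p = 0.00139, and adjusted p = 0.347 with an estimated correlation), with Stat3 at 1.57 and Cxcl2 at 5.07. For these 7 lists too, the counts adjusted over the list alone were the same. The bound for Ccl8, with no count in Cisplatin, left the inflammatory median unchanged. Fallen interferon genes numbered 8 without Cisplatin replicate 3. Risen macrophage markers numbered 1 without Normal replicate 1 or Cisplatin replicate 2.

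Over all 12859 genes tested in Cisplatin against Normal, 3382 rose and 3630 fell by edgeR's quasi-likelihood test, which is 54.5% of the genes. The 2 groups did not overlap for 62.2% of genes, against 10% by chance for 3 libraries against 3. Of the 32 lists, 24 were called by camera with the preset correlation. With an estimated correlation 0 were called, the smallest adjusted p being 0.102, although 10 had an unadjusted p under 0.05, and fry called 30. With 54.5% of genes called, fry passes most lists whatever their members, since it does not set them against other genes. The labels name separate samples and do not state that each came from its own mouse, so the p-values measure the spread between these samples.

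The comparison of RP with Cisplatin asks how giving RP changed the muscle of cisplatin-treated mice. No group received RP without cisplatin, so an effect of RP alone cannot be told apart from one on the cisplatin response. Fbxo32 fell to 500 ± 189 CPM, a log2 fold change of -4.33 ± 0.29 (adjusted p = 2.41e-07), and Trim63 to 615 ± 170 CPM, -4.07 ± 0.23 (adjusted p = 8.11e-08). Of the 20 muscle E3 ligases 8 fell, 2 rose (Fbxo21 at 1.29 and Trim32 at 1.16) and 10 were not called (median -0.23, camera adjusted p = 0.000657, and adjusted p = 0.225 with an estimated correlation). Over all genes tested, 48.8% were called in RP against Cisplatin. Proteasome genes fell in 35 of 38 cases (median -1.27, camera adjusted p = 1.85e-24, and adjusted p = 0.208 with an estimated correlation), Psmd8 by 2.02. Autophagy genes fell in 14 of 25 (median -0.43, camera adjusted p = 9.31e-06, and adjusted p = 0.208 with an estimated correlation), Gabarapl1 by 2.63. Glucocorticoid and FoxO responsive genes fell in 17 and rose in 2 of 25 cases (median -0.85, camera adjusted p = 5.72e-06, and adjusted p = 0.225 with an estimated correlation). The metallothioneins Mt1 (-5.22) and Mt2 (-5.09), Acot1 (-5.08), AA467197 (-4.41) and Chil3 (-4.37) had the largest falls among genes with a mean of at least 5 CPM and non-overlapping groups. With p adjusted over the list alone, 18 glucocorticoid and FoxO responsive genes fell, and the counts of the other 3 lists were the same. Risen glucocorticoid and FoxO responsive genes numbered 1 with DESeq2 or without Normal replicate 3 or Cisplatin replicate 1 or 2 or RP replicate 1 or 3.

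Stress, inflammatory and fatty acid gene lists fell in RP against Cisplatin. Of 28 p53 and DNA damage genes 14 fell, 3 rose and 11 were not called (median -0.71, camera adjusted p = 0.00188, and adjusted p = 0.225 with an estimated correlation). Cdkn1a fell by 2.99, whereas Gdf15 was at 19.5 ± 8.31 CPM in Cisplatin and 11.6 ± 2.97 in RP (adjusted p = 0.0762), and Eda2r at 19.8 ± 6.86 and 18.4 ± 5.43 (adjusted p = 0.772). Heat shock genes fell in 12 of 18 cases (median -0.67, camera adjusted p = 1.89e-05, and adjusted p = 0.208 with an estimated correlation), Hspb1 being at 333 ± 14.7 CPM in RP. The antioxidant list fell in 13 and rose in 3 of 21 (median -0.71, camera adjusted p = 0.000146, and adjusted p = 0.152 with an estimated correlation), the integrated stress list fell in 7 and rose in 2 of 16 (median -0.36, camera adjusted p = 0.0279, and adjusted p = 0.225 with an estimated correlation), and inflammatory genes fell in 14 and rose in 3 of 19 (median -1.16, camera adjusted p = 0.00136, and adjusted p = 0.293 with an estimated correlation). Fatty acid genes fell in 11 and rose in 1 of 28 cases (median -0.36, camera adjusted p = 0.000248, and adjusted p = 0.410 with an estimated correlation). Neutrophil markers fell in 5 of 6 (median -2.54, camera adjusted p = 0.0366, and adjusted p = 0.370 with an estimated correlation), a call lost without Cisplatin replicate 1 (0.0911) or without Cisplatin replicate 2 (0.0543) or without RP replicate 1 (0.0510), within a range of 0.00369 to 0.370. With p adjusted over the list alone, 10 fatty acid genes fell, and the counts of the other 6 lists were the same. Fallen neutrophil markers numbered 3 with DESeq2 or without RP replicate 1 or 3 and 2 with limma-voom or without Cisplatin replicate 1 or 2 or RP replicate 2. Fallen inflammatory genes numbered 9 without Cisplatin replicate 2 or RP replicate 2. Risen fatty acid genes numbered 2 without Cisplatin replicate 2 or RP replicate 3. Risen heat shock genes numbered 1 without Cisplatin replicate 2.

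Fast fibre, glycolysis and oxidative phosphorylation genes rose in RP against Cisplatin. Casq1 came to 829 ± 256 CPM (3.99 ± 0.24, adjusted p = 1.28e-07), and 11 of 18 fast fibre genes rose with none falling (median 0.92, camera adjusted p = 5.42e-05, and adjusted p = 0.225 with an estimated correlation). Of 16 slow fibre genes, 2 rose and 2 fell, with no list call (camera adjusted p = 0.698, and adjusted p = 0.892 with an estimated correlation). Glycolysis genes rose in 13 and fell in 4 of 20 cases (median 0.85, camera adjusted p = 9.81e-07, and adjusted p = 0.208 with an estimated correlation), Gpd1 by 3.06. Oxidative phosphorylation genes rose in 50 and fell in 1 of 76 (median 0.49, camera adjusted p = 4.59e-06, and adjusted p = 0.428 with an estimated correlation). Satellite cell and embryonic genes rose in 8 and fell in 5 of 19 (median 0.68, camera adjusted p = 0.0381, and adjusted p = 0.208 with an estimated correlation), a call lost without RP replicate 3 (0.0696), within a range of 9.05e-05 to 0.208. Circadian genes rose in 9 and fell in 6 of 17 (median 0.68, camera adjusted p = 0.0348, and adjusted p = 0.208 with an estimated correlation), with Dbp at 4.53 and Arntl at -3.82, again with collection times not given. The growth factor list (9 up and 7 down of 25, camera adjusted p = 0.434), the neuromuscular junction list (6 up and 3 down of 12, camera adjusted p = 0.420), the immediate early list (3 up and 9 down of 20, camera adjusted p = 0.160) and the cell cycle list (1 up and 4 down of 15, camera adjusted p = 0.112) were not called. The immediate early list was called without Cisplatin replicate 3 (0.0299), within a range of 0.0299 to 0.585. Counts adjusted over the list alone were 9 risen satellite cell genes and 10 risen growth factor genes, and those of the other lists named here were the same. Fallen satellite cell genes numbered 3 without Cisplatin replicate 2 or 3, 2 without RP replicate 1 and 1 without RP replicate 2. Fallen immediate early genes numbered 5 without Cisplatin replicate 2 or RP replicate 2. Fallen circadian genes numbered 3 without RP replicate 2. Risen slow fibre genes numbered 4 with limma-voom or without Normal replicate 2 and 8 without Cisplatin replicate 1.

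Tendon, fibroblast, adipocyte and several other marker lists rose in RP against Cisplatin, but neutrophil markers fell and the endothelial list was not called. All 9 tendon markers rose (median 3.15, camera adjusted p = 0.000125, and adjusted p = 0.225 with an estimated correlation), 14 of 15 fibroblast markers rose (median 2.36, camera adjusted p = 1.17e-12, and adjusted p = 0.208 with an estimated correlation), and collagen and matrix genes rose in 21 and fell in 2 of 28 cases (median 1.97, camera adjusted p = 1.39e-08, and adjusted p = 0.227 with an estimated correlation). Interferon response genes rose in 22 of 27 (median 1.79, camera adjusted p = 4.78e-08, and adjusted p = 0.227 with an estimated correlation), Psmb9 by 3.21 and Igtp by 3.15. Adipocyte markers rose in 11 and fell in 1 of 13 (median 2.81, camera adjusted p = 0.000102, and adjusted p = 0.309 with an estimated correlation), and lymphocyte markers rose in 4 of 6 (median 3.41, camera adjusted p = 2.83e-05, and adjusted p = 0.208 with an estimated correlation). Macrophage markers rose in 11 and fell in 2 of 18 (median 1.23, camera adjusted p = 0.00934, and adjusted p = 0.455 with an estimated correlation). Schwann cell markers rose in 8 of 12 (median 1.47, camera adjusted p = 0.00397, and adjusted p = 0.349 with an estimated correlation), and smooth muscle markers rose in 10 and fell in 1 of 12 (median 1.49, camera adjusted p = 3.70e-05, and adjusted p = 0.208 with an estimated correlation). Erythroid genes rose in 6 of 7 (median 2.34, camera adjusted p = 0.0128, and adjusted p = 0.410 with an estimated correlation), with Hba-a1 reaching 168 ± 109 CPM. Without Hbb-b1 and Hbb-b2, 4 of the 5 others rose (median 2.34, camera adjusted p = 0.0322, and adjusted p = 0.393 with an estimated correlation). The endothelial list was not called (6 up and 2 down of 15, camera adjusted p = 0.150, and adjusted p = 0.585 with an estimated correlation). It was called without Cisplatin replicate 1 (0.0437) or without RP replicate 3 (0.0473), within a range of 0.0437 to 0.585. With p adjusted over the list alone, 25 interferon, 13 macrophage and 5 lymphocyte genes rose, and the counts of the other 8 lists were the same. Risen erythroid genes numbered 3 with limma-voom. Risen tendon markers numbered 5 with limma-voom. Fallen collagen and matrix genes numbered 1 without Cisplatin replicate 1. Fallen endothelial markers numbered 1 with limma-voom or without Cisplatin replicate 1 or 2 or RP replicate 2 or 3, and fallen smooth muscle markers 0 without Cisplatin replicate 1 or 3 or RP replicate 1 or 2.

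In RP against Cisplatin 3167 genes rose and 3110 fell by edgeR's quasi-likelihood test, which is 48.8% of the genes. Of the genes called in Cisplatin against Normal, 5563 (79.3%) were called with the opposite sign in RP against Cisplatin. In Cisplatin, 2773 of them were higher and 2790 lower than in both parallel groups, Normal and RP. The genes ranked at the top of this set were Hspb1, Dbp, Acot1, Gpd1, Myoc and Sypl2. Ciart and Nr1d1, repressors of the circadian clock, were the 2 genes called with the same sign in both comparisons. Independent lists of these sizes would share 1712 genes of opposite sign. Both comparisons use the Cisplatin libraries, and 20 simulations of unchanged groups gave 0 such genes. Unchanged groups give few calls in either comparison, so this 0 does not show what sharing gives when Cisplatin differs. Across genes, which are not independent replicates, the fold changes had a correlation of -0.936 against a simulated -0.497, and a covariance of -1.44 against -0.05. In a fit chosen after seeing the data, the Cisplatin libraries were parted in each of 6 ways so that none served both comparisons, a part of 1 library being assumed to vary like the other groups. The correlation was then -0.807 to -0.734, the covariance -1.52 to -1.41, and 3090 to 4255 genes were called with opposite signs and 2 to 13 with the same sign. Of the 32 lists, 26 were called with the preset correlation. With an estimated correlation 0 were called, the smallest adjusted p being 0.152, although 5 had an unadjusted p under 0.05, and fry called 29.

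**Figure D2:**
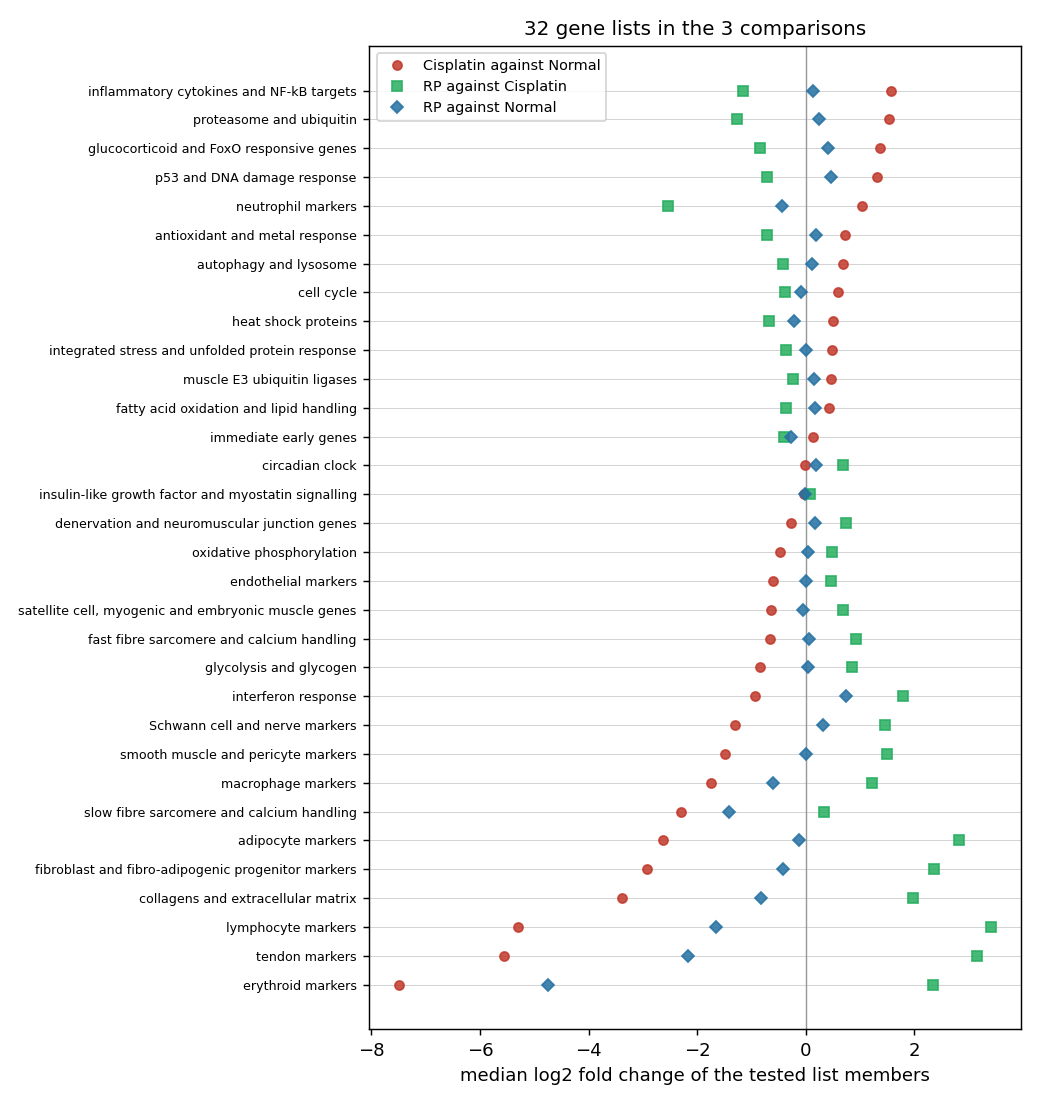
Median log2 fold change of the tested members of each of 32 gene lists (x axis) in the 3 comparisons (circles, squares and diamonds). Proteasome genes sit at 1.53, -1.27 and 0.25, erythroid genes at -7.49, 2.34 and -4.74.

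The comparison of RP with Normal asks which genes still differed from untreated muscle. Among 12859 genes tested 24 were higher and 41 lower in RP by edgeR, while 1649 had an unadjusted p under 0.05. Fbxo32 (0.39 ± 0.26, adjusted p = 0.566) and Trim63 (0.18 ± 0.20, adjusted p = 0.776) were not called, and none of the 20 muscle E3 ligases passed with edgeR, over all genes or adjusted over the list alone, while 3 had an unadjusted p under 0.05 and 0 passed with DESeq2 or limma-voom. Fbxo32 was at 0.14 without RP replicate 3 and 0.66 without RP replicate 2, and Trim63 at -0.05 and 0.35 without these, 0.11 without Normal replicate 1 or 3 and 0.34 without Normal replicate 2. With the Rn45s share as a covariate, chosen after seeing the data, they were at 0.99 and 0.67, and none of these fits called them. The E3 list was not called (camera adjusted p = 0.102, and adjusted p = 0.584 with an estimated correlation). It was called upward without Normal replicate 2 (0.0145) or without RP replicate 2 (0.0125), within a range of 0.00161 to 0.584 over the alternatives. Genes of the p53 response stayed higher: Cdkn1a was 5.03 times as high as in Normal (2.33 ± 0.22, adjusted p = 0.000385), Gdf15, a secreted stress factor, was at 11.6 ± 2.97 CPM against 0.440 ± 0.305 (4.69 ± 0.51, adjusted p = 0.000750), and Trp53inp1 (1.13) and Eda2r (1.54) were higher too. These were 4 of 28 p53 list members, or 14 adjusted over the list alone (median 0.47, camera adjusted p = 5.32e-16, and adjusted p = 0.0389 with an estimated correlation). All 7 erythroid genes stayed lower (median -4.74, camera adjusted p = 2.34e-44, and adjusted p = 0.0333 with an estimated correlation), with Hba-a1 at -4.68 and Alas2, the haem synthesis enzyme of red cells, at -3.73. Hbb-b1 and Hbb-b2 almost repeat the counts of Hbb-bs and Hbb-bt, and without them 63 genes were called and 5 of the 5 others were lower (median -4.68, camera adjusted p = 1.79e-33, and adjusted p = 0.0278 with an estimated correlation). Tendon markers were lower in 3 of 9 cases, Fmod (-2.12), Chad (-3.41) and Thbs4 (-1.97), or 8 adjusted over the list alone (median -2.17, camera adjusted p = 4.54e-18, and adjusted p = 0.0456 with an estimated correlation). The Trp53inp1 and Eda2r calls were each lost without Normal replicate 1 or 3, RP replicate 1 or 3, or Cisplatin replicate 1 or 2 (adjusted p up to 0.241 and 0.222). The Thbs4 call was lost without Normal replicate 1 or RP replicate 1 or 3 (up to 0.197) and the Chad call without Normal replicate 1 (0.0608). Gdf15, Alas2 and Fmod kept their calls without each library, but not in every other setting. With the Rn45s share as a covariate, 18 of the 32 called genes named by the rule in RP against Normal lost their call. Erythroid, p53 and tendon were the 3 lists called with an estimated correlation, of 18 called with the preset one. With 1 library left out and an estimated correlation, a test chosen after seeing the data, the erythroid call was lost without Normal replicate 2 (0.0547). The tendon call was lost without any library but Normal replicate 1 (0.0408 without it, up to 0.112 without RP replicate 3). The p53 call was lost without any library but Cisplatin replicate 3 (0.0269) or RP replicate 2 (0.0476), up to 0.112 without RP replicate 3. Higher p53 genes numbered 8 with DESeq2 and 2 without Normal replicate 1 or 3 or Cisplatin replicate 1 or 2 or RP replicate 1 or 3. Lower tendon markers numbered 5 with DESeq2 or without Normal replicate 2, 1 without Normal replicate 1 and 6 without Cisplatin replicate 3.

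Some single antigen presentation and clock genes also differed between RP and Normal. Cd74 (-2.04), H2-Ab1 (-1.86), H2-Eb1 (-1.62), H2-Aa (-1.69) and the chemokine receptor gene Ccr2 (-2.04) were lower. The first 4 belong to the lymphocyte list, of whose 20 members 6 were tested (4 adjusted over the list alone, camera adjusted p = 4.80e-13, and adjusted p = 0.0508 with an estimated correlation). Ciart (2.63 ± 0.35, adjusted p = 0.00317), Nr1d1 (1.11) and Per1 (0.96) were higher, 3 of 17 circadian genes (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.000155, and adjusted p = 0.0508 with an estimated correlation), and collection times, which bear on clock genes, are not given. The interferon list was called upward with Igtp (1.47) and Tap1 (1.46) as its 2 called members of 27, or 8 adjusted over the list alone (median 0.73, camera adjusted p = 2.47e-15, and adjusted p = 0.195 with an estimated correlation). Mt2 (adjusted p = 0.0425, 240 ± 149 CPM in RP and 59.8 ± 16.4 in Normal), the glycolytic regulator Pfkfb3 (1.73) and the mitochondrial carrier Slc25a25 (1.43) were higher, and Actc1 (-1.88) and Col1a2 (-1.85) lower. Proteasome genes had a median of 0.25 with 1 member called, Psmd8 (0.82), or 7 adjusted over the list alone (camera adjusted p = 8.74e-10, and adjusted p = 0.360 with an estimated correlation). Collagen and matrix genes had a median of -0.82 with 1 member called, or 13 adjusted over the list alone (camera adjusted p = 8.15e-14, and adjusted p = 0.195 with an estimated correlation). Leaving out Normal replicate 1 or RP replicate 1 ended the calls of H2-Ab1, H2-Eb1, H2-Aa, Per1, Igtp, Tap1, Mt2, Actc1, Col1a2 and Psmd8. Leaving out RP replicate 3 ended these calls except that of H2-Ab1, and Normal replicate 3 all except those of H2-Ab1 and H2-Eb1. Cisplatin replicate 2 decided H2-Aa, Tap1, Mt2, Actc1, Col1a2 and Psmd8, Cisplatin replicate 1 the last 4 of these, and Normal replicate 2 H2-Aa, Tap1 and Psmd8. The highest adjusted p ran from 0.0780 for H2-Eb1 to 0.275 for Col1a2. Nr1d1, Pfkfb3 and Ccr2 kept their calls without each library, but not in every other setting. Lower lymphocyte markers numbered 1 without Normal replicate 1 or RP replicate 1 and 2 without RP replicate 3. Higher interferon genes numbered 4 with DESeq2, 0 without Normal replicate 1 or 3 or RP replicate 1 or 3 and 1 without Normal replicate 2 or Cisplatin replicate 2. Lower collagen genes numbered 8 with DESeq2, 2 with limma-voom or without Normal replicate 2 or Cisplatin replicate 3, 0 without Normal replicate 1 or 3 or Cisplatin replicate 1 or 2 or RP replicate 1 or 3 and 7 without RP replicate 2.

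The other lists had few or no called members in RP against Normal with edgeR. Glucocorticoid and FoxO responsive genes were called upward by camera with Per1 and Mt2 as called members (10 adjusted over the list alone, camera adjusted p = 8.74e-10, and adjusted p = 0.195 with an estimated correlation). Antioxidant genes were called upward with Mt2 (4 adjusted over the list alone, camera adjusted p = 0.00400, and adjusted p = 0.0735 with an estimated correlation). Autophagy genes were called upward as a list with 0 members called and 9 at an unadjusted p under 0.05 (2 with DESeq2, 4 adjusted over the list alone, camera adjusted p = 0.00593, and adjusted p = 0.382 with an estimated correlation). Slow fibre genes were called downward with 0 members called and 11 at an unadjusted p under 0.05 (0 with DESeq2, 8 adjusted over the list alone). Their median was -1.42 (camera adjusted p = 3.77e-05, and adjusted p = 0.368 with an estimated correlation), and the call was lost without Normal replicate 3 (0.0526), within a range of 2.68e-17 to 0.368. Lower slow fibre genes numbered 3 without Normal replicate 2. In that library the 11 slow fibre genes that fell in Cisplatin had a mean log2 CPM of 4.82, against 7.09 and 7.82 in Normal replicates 1 and 3. Macrophage markers (6 at an unadjusted p under 0.05, 2 called with DESeq2, 3 down adjusted over the list alone, camera adjusted p = 4.96e-05, and adjusted p = 0.382 with an estimated correlation) were called downward. So were fibroblast markers (6 at an unadjusted p under 0.05, 2 called with DESeq2, 1 up and 3 down adjusted over the list alone, camera adjusted p = 0.000318, and adjusted p = 0.360 with an estimated correlation). Higher glucocorticoid and FoxO responsive genes numbered 8 with DESeq2 or without Normal replicate 2, 1 with limma-voom or without Cisplatin replicate 1 or 2, 0 without Normal replicate 1 or 3 or RP replicate 1 or 3 and 5 without RP replicate 2. Higher antioxidant genes numbered 2 with DESeq2, 0 with limma-voom or without Normal replicate 1 or 3 or Cisplatin replicate 1 or 2 or RP replicate 1 or 3 and 3 without RP replicate 2.

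Other list calls between RP and Normal depended on single libraries. Fatty acid genes were called upward (camera adjusted p = 0.0148, and adjusted p = 0.681 with an estimated correlation), but not without Normal replicate 1 (0.641) or without RP replicate 3 (0.368), within a range of 5.79e-07 to 0.681. Integrated stress genes were called upward with Gdf15 as the called member (camera adjusted p = 0.0279, and adjusted p = 0.297 with an estimated correlation), but not without Normal replicate 1 (0.225) or without RP replicate 3 (0.0779), within a range of 0.00370 to 0.298. Immediate early genes were called downward (4 adjusted over the list alone, camera adjusted p = 0.00400, and adjusted p = 0.457 with an estimated correlation), but not without Normal replicate 1 (0.231) or without RP replicate 2 (0.231), within a range of 4.09e-09 to 0.457. Heat shock genes were called downward (camera adjusted p = 0.0446, and adjusted p = 0.506 with an estimated correlation), but not without Cisplatin replicate 2 (0.0523) or without Cisplatin replicate 3 (0.0626) or without Normal replicate 3 (0.386) or without RP replicate 1 (0.227) or without RP replicate 2 (0.105), within a range of 0.0111 to 0.993. Lists not called were inflammatory genes (camera adjusted p = 0.204, called without RP replicate 2 (0.0192)), satellite cell genes (camera adjusted p = 0.122, called without RP replicate 3 (0.0258)) and oxidative phosphorylation genes (camera adjusted p = 0.394, called without Normal replicate 3 (0.000221) or without RP replicate 3 (0.0435)). Schwann cell markers were not called (camera adjusted p = 0.294) but were without Normal replicate 2 (0.0157) or without RP replicate 3 (0.0338). Adipocyte markers (camera adjusted p = 0.560) were called downward without Normal replicate 1 (8.83e-07) and upward without Normal replicate 2 (0.000333). Neutrophil markers (camera adjusted p = 0.811) were called downward without Normal replicate 2 (0.0223).

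Fast fibre (camera adjusted p = 0.352), neuromuscular junction (camera adjusted p = 0.605), glycolysis (camera adjusted p = 0.461), growth factor (camera adjusted p = 0.394) and cell cycle genes (camera adjusted p = 0.394) were not called between RP and Normal. Endothelial (camera adjusted p = 0.665) and smooth muscle markers (camera adjusted p = 0.811) were not called either. Counts adjusted over the list alone were 1 up and 1 down for neuromuscular junction genes and 1 up and 3 down for growth factor genes. They were 1 up for inflammatory genes, 1 up and 1 down for neutrophil markers and 1 down for adipocyte markers. The neutrophil list had a median of -0.43 and a mean of -0.36 with a camera direction upward, and the glycolysis list a median of 0.04 and a mean of -0.01 with the direction upward. The endothelial and smooth muscle lists had medians above 0 and means of -0.05 and -0.03 with the direction downward.

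Of the 65 genes called between RP and Normal, 57 were also called between Cisplatin and Normal, 55 of them with the same sign. Independent lists of these sizes would share 35.4 genes, 17.9 of them with the same sign. In 20 simulations of unchanged groups, where few genes are called at all, 0 to 1 were shared. The comparisons share the Normal libraries, which alone makes signs agree: 58 of the 65 genes had the same sign in both, against 57 to 63 of the 65 genes of smallest p in the simulations, and over all genes 66.8% did against a simulated 66.9%. Neither share of signs exceeded that of unchanged groups. Those groups lack the cisplatin change: the variance of their Cisplatin against Normal fold changes was 0.11, against 1.77 observed. Shared noise therefore weighs more on their signs, and these shares cannot decide whether agreement remains. With the Normal libraries parted in each of 6 ways so that none served both, chosen after seeing the data, 16 to 76 genes were called in both, 16 to 62 with the same sign and 0 to 14 with opposite signs. The correlation was then 0.275 to 0.428, the covariance 0.24 to 0.31, and 59.1 to 63.5% of all genes had the same sign. With all libraries, the fold changes had a correlation of 0.524 across genes, which are not independent replicates, against 0.508 in simulated unchanged groups, and a covariance of 0.33 against a simulated 0.06. The slope of RP against Normal on Cisplatin against Normal, corrected for the shared libraries, was 0.167. The risen genes of Cisplatin kept a median of 16.1 ± 8.38% (SD, n = 3) of their log2 difference in RP, risen E3 ligases 8.95 ± 7.42%, risen p53 genes 40.8 ± 7.21% and the fallen erythroid genes 70.9 ± 19.3%. The count of 65 was 22 without Normal replicate 1 or RP replicate 1, 28 without RP replicate 3, 33 without Normal replicate 3, 40 without Cisplatin replicate 2, 100 without Normal replicate 2, 102 without Cisplatin replicate 3 and 116 without RP replicate 2. It was 229 with DESeq2, 293 with no filter on low counts and 21 with the Rn45s share as a covariate, a setting chosen after seeing the data.

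**Figure D3:**
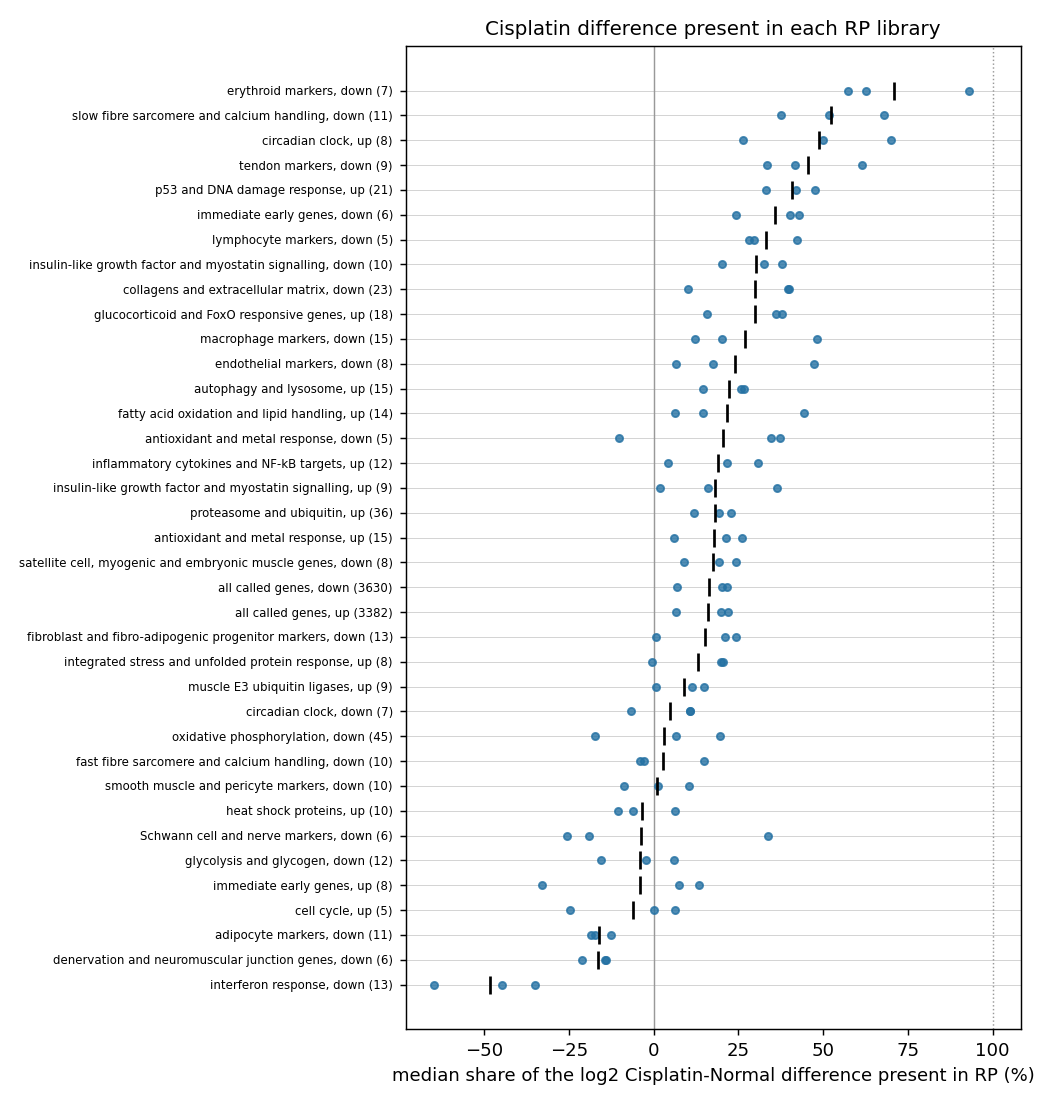
Median share of the log2 difference between Cisplatin and Normal that was present in each of 3 RP libraries (points, in %), with the mean as a bar, for the called members of each list (number in brackets). Erythroid genes lie at 57.2 to 93.0% and the risen muscle E3 ligases at 0.595 to 14.8%.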

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

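Leaving out Rn45s, the Rn45s covariate, leaving out Hbb-b1 and Hbb-b2, parting a shared group, and leaving out each library with an estimated correlation were the tests chosen after the results were seen. Without those 2 symbols, 7011, 6275 and 63 genes were called and no list call changed. The counts of 7012 and 6277 changed genes stayed within 1.5 times under every alternative, from 6046 to 7076 in Cisplatin against Normal and from 5211 to 6325 in RP against Cisplatin, and 0 genes shared with the reported calls changed sign. Apart from Fbxo32 and Trim63, which were tallied separately, the rule named 135 genes in Cisplatin against Normal. All 135 kept their call in every setting in which they were tested, as did 132 of 135 in RP against Cisplatin (not Cxcr2, Hba-a2 and S100a8). In RP against Normal 10 of 32 did: Cd74, Cdkn1a, Ciart, Slc25a25 and 6 globin symbols. The causes of the following changes were not tested. In RP against Normal, 65 changed genes became 229 with DESeq2, 293 with no filter on low counts, 21 with the Rn45s share as a covariate and 22 to 116 with 1 library left out. With an estimated inter-gene correlation, 0, 0 and 3 lists were called in Cisplatin against Normal, RP against Cisplatin and RP against Normal, where 24, 26 and 18 were reported, and fry called 7 in the last. The muscle E3 ligase list then had an adjusted p of 0.182 in Cisplatin against Normal and 0.225 in RP against Cisplatin. In RP against Normal (adjusted p = 0.102) the E3 list was called upward with no filter (0.0496), with the Rn45s covariate (0.00161), and without Normal replicate 2 (0.0145) or RP replicate 2 (0.0125), and its p ran from 0.0125 to 0.429 with 1 library left out. Without Normal replicate 2 the adipocyte list turned upward (0.000333) and the neutrophil list downward (0.0223) in RP against Normal; with 1 library left out their p ran from 8.83e-07 to 0.483 and from 0.0223 to 0.738. Same-numbered libraries of different groups had correlations of -0.12 to 0.16 in their deviations, and 3 of 9 such libraries matched their own number best, so the numbers were not taken as pairs; with the replicate block 6988, 6292 and 61 genes were called. With 3 libraries a group, simulations recovered 44 to 52% of genes changed by a log2 of 1. Few genes changed in them: 12374 of 12574 were unchanged in the simulated Cisplatin against Normal, where 54.5% of the real genes were called. Recovery and scaling with so many changed genes were not simulated.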

Other observations

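In this part the gene and list calls on all 9 libraries were planned, with the estimated correlation and fry for the interferon list. The fits of the 2 compared groups alone, which are the real splits, were planned too. All other tests in this part were chosen after the result they concern had been seen. Slow fibre genes varied together between libraries of 1 group. Myl3 was at 1124 and 2400 CPM in Normal replicates 1 and 3 and at 102.0 in Normal replicate 2, and at 140 in Cisplatin replicate 1 against 2.76 and 20.5 in the others. The 13 interferon genes that fell with cisplatin had a median share of -48.2 ± 15.2% (SD, n = 3) of the cisplatin difference in RP, but 2 of the 27 members tested were called between RP and Normal, Igtp of the 13 and Tap1 outside them, and the list was not called with an estimated correlation (0.195) or fry (0.122). Over all genes that fell with cisplatin, RP replicates 1, 2 and 3 had median shares of 20.3, 6.99 and 21.7%.

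Slow fibre genes may differ in Cisplatin because each sample held a different share of slow-fibre muscle. The 11 fallen slow fibre genes had a mean pairwise correlation of 0.859 in their deviations within groups, against a 95th percentile of 0.217 in 10000 random sets of matched expression. Such a difference in share predicts this, but so does joint regulation of the genes, and random sets cannot tell these apart. The inter-gene correlation estimated by camera was 0.558 for the slow fibre list and 0.551 for the proteasome list. An effect of cisplatin itself cannot be told apart from a difference in share either. The mean log2 CPM of the 11 genes overlapped between the groups, with an exact two-sided permutation p of 0.2 where 0.1 is the smallest that 3 against 3 libraries can give.

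With an estimated correlation 0 of the 32 lists were called in Cisplatin against Normal. At the preset correlation most marker lists of other cell types were called lower in Cisplatin, though the neutrophil and endothelial lists were not called. A lower share of all such tissue would lower every marker list alike, but tendon markers fell further than endothelial ones in each Cisplatin library, by a mean difference of -4.01 (SD 0.38, n = 3) on the log2 scale. Lower depth would need fewer counts, and the mean total in Cisplatin was 1.15 times that in Normal. An effect of cisplatin on these cells, and a difference in how tendon, fat and blood were removed with the muscle, were not tested and stay open, since they go with the group.

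The p53 list, with 4 of its 28 tested members called, and all 7 erythroid symbols stayed away from Normal in RP. With 1 library left out and an estimated correlation, the p53 list call held only without Cisplatin replicate 3 or RP replicate 2. RNA of Cisplatin samples mixed into the RP libraries would leave the same linear share of the cisplatin change in every gene, but the 21 risen p53 genes kept a median share larger than other risen genes by 9.80 percentage points (SD 4.73, n = 3, permutation p = 0.018 over 10000 random sets), which is little over 2 SD, and the 7 erythroid symbols, of which 2 pairs hold almost the same counts, one larger by 69.5 (SD 9.55, 63.3 to 80.5 over the RP libraries), or by 69.4 with 1 symbol of each pair. A single Normal library with low p53 genes was argued against: without each in turn the p53 list median in RP lay at least 0.48 above the 2 others on the log2 scale, over 4 times the pooled SD of 0.11, and fry gave an adjusted p of 0.0258 to 0.0380. A p under 0.05 with an estimated correlation was first required as well and was dropped when it was not met (0.0542 to 0.0809), as it was above 0.05 without 2 of the Cisplatin and 2 of the RP libraries too. In linear CPM both sets thus kept a larger share than other changed genes. Both were picked after they were seen to stay apart from Normal, and the random sets were not matched for the size of the change. The tests therefore bear on mixing and do not show that these sets are particular. Why they kept more is open. On the log2 scale a larger share is not particular to p53 genes: fallen slow fibre, risen circadian and fallen tendon genes kept 52.4, 48.9 and 45.5% against 40.8%.

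Other splits of the libraries were run to ask about chance. For each comparison the 6 libraries make 10 splits, too few for a share under 0.05, and each of the other splits keeps 2 libraries of a group against 1, so that part of the real difference remains in it. In Cisplatin against Normal 1 split, the real one, gave as many as 6728 genes, and the highest other gave 0; in RP against Cisplatin the values were 5897 and 0, and in RP against Normal 67 and 1. Called gene lists numbered 25 against 19 in the highest other split, 25 against 21, and 17 against 16, so that camera with the preset correlation called lists in splits with 0 or 1 called genes. The E3 ligase list had an unadjusted camera p of 7.59e-05 against 0.00307 in the smallest other split, 0.000414 against 0.00367, and, in RP against Normal, 0.0783 against 9.27e-05, where 5 of the 10 splits gave a p as small. For the 5563 genes of opposite sign, 100 splits of the 9 libraries into 3 groups were used, the real one included. Only the real one gave as many, and the highest other gave 0. The other splits mix the groups, which widens the spread within each and by itself lowers the calls. Their 0 therefore cannot decide whether the division arose by chance. Differences that go with the group, such as collection, were not tested by these splits.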
